A study of Mus musculus with 7 samples.

How the data were processed

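Whole bone marrow of mice, taken from spine, hips, femur and tibia and depleted of red cells, had been sequenced with a droplet 3′ kit in 7 libraries that fall into 4 pools. Several samples shared each pool, and every one of the 20 samples was marked with its own hashtag antibody. Per the labels, the kit and the HiSeq4000 sequencer were named for all libraries. The labels give no treatment. The series text states a condition for HRO.5 and HRO.6 only, which it calls TET2-mutated chronic samples.

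The deposited files hold raw UMI counts per gene and cell barcode, with no normalisation, for 31053 genes. Per the file headers, the matrix of pool WBM_1 was written by Cell Ranger 3.0.0 and those of the other pools by Cell Ranger 3.1.0. Per the submitters' processing notes, bcl2fastq, Cell Ranger, Seurat and the mm10 build were used. The gene annotation and the rule that kept barcodes are not given in the sources used here. Hashtag counts, also deposited as whole-number counts, are a separate table for WBM_1 and extra features of the matrix for the other pools. The start AAACCT is found in 0.169% of the WBM_1 barcodes and in none of the other libraries, and the start AAACCC in none of WBM_1 and in 0.0576% to 0.126% of the others, so the barcode list of WBM_1 appears to be another one.

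Hashtags were assigned in each library with HTODemux of Seurat 5.3.0 at a positive quantile of 0.99, the method named in the series text, and singlets were kept. The fixed plan for the centred log-ratio of the hashtag counts could be read as across cells or within each cell. The form across cells was chosen after the hashtag assignments were compared and ahead of any gene test, and it gave HRO.5 1204 singlets against 586 with the other form. Libraries WBM_3a and WBM_3b shared 2078 barcodes, against 51 for the next pair, and in each shared pair the copy with fewer UMIs was removed. Of 78720 barcodes, 57944 were singlets. Cells with under 300 genes (4540) and then cells with at least 10% mitochondrial counts (10368) were removed, which left 43024 cells once lower-UMI copies among the singlets were also gone.

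Counts were log-normalised in scanpy 1.11.5. The 2000 most variable genes within libraries, 30 principal components and a graph of 20 neighbours entered Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1, with no integration across pools. This gave 40 clusters. They were named from 19 marker lists fixed in advance, by a rule set after the data were seen. A cluster took the class with the most markers found in over 10% of its cells at over 2-fold the rest. It stayed unnamed with under 3 such markers, a tie between classes, or more leading genes of another class among the top 10. Low UMIs with no own marker among the top 10 also left it unnamed. Cluster 26 (a tie) and cluster 33 (low UMIs), with 74.7% and 59.6% of cells from HRO.7, stayed unnamed in this way. 5 clusters stayed unnamed and the rest formed 13 classes. All class names below stand for cells that resemble the class by these markers. Clusters split by pool as well as by type. Whether the lack of integration caused this was not tested.

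Scrublet called 8.53% of barcodes in WBM_1 and 3.04% to 3.43% in the WBM_2 libraries, and 0%, 0.0133% and 0.0160% in WBM_3a, WBM_3b and WBM_4, where it did not work. Doublets were therefore removed only by hashtag in the values reported, and removing the top 5 percent of Scrublet scores in each library was added as an alternative.

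Cells are not replicates. Counts were summed per hashtag sample and class, samples with at least 20 cells of the class entered, and all groups of at least 2 samples were fitted together. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05, with group and pool as terms. The chronic samples exist in WBM_1 alone, and HRO samples in no part of WBM_1. The fixed plan set a pool term where every compared group is spread over pools and the contrast can be estimated, otherwise group alone. The chronic samples are not spread over pools. The term can still be estimated through WTY.3, WTO.3 and HRY.4 of WBM_1, so it was kept, which departs from the wording of the plan. The counts with and without the pool term were seen together. Folds are log2 values from this fit. Each standard error is the absolute fold divided by the square root of the F value of its test. A prior count of 2 was used only for the log CPM values behind camera, the differences within pools and the deviations from group means.

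The plan, the groups, 16 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. The rule names, per class and comparison, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with a mean of at least 20 CPM, up to 4 members of each list that passed, and Tet2 always. Immunoglobulin and T cell receptor segments, Xist and Y-linked genes, haemoglobins and gene names of the Gm or Rik kind were counted without being named among the 16. Where fewer than 6 genes passed, all were named. Class shares per sample were compared with exact two-sided permutation tests (scipy 1.17.1), adjusted over the 13 classes. Samples HR.7 and HR.AE are alone in their groups and entered no test, and their intervals (exact Poisson or Clopper-Pearson, 95%) cover counting error only. HRO against WTO in neutrophils and progenitors was added to the reported comparisons after the data were seen. Fits were also made for T or NK cells, B lineage cells and all cells together and are not reported here.

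The same procedure was tested on simulated data with 200 changed genes drawn on the real monocyte means and library sizes. For chronic against HRO (10117 genes) it recovered 44% of 2-fold and 89% of 4-fold changes, and 7 of its 140 calls were false. For HRO against WTO (10115 genes) it recovered 95% and 100%, and 15 of 210 calls were false. These rates describe the simulated data only. In the real monocytes the deviations of HRO.7 and HRO.8 from their group mean correlated at 0.807 across genes. The real count for HRO against WTO ranged from 63 to 1672 with a sample left out. Whether the rates hold for data with such a structure was not tested.

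Sample numbers in the labels recur across groups. In monocytes, the deviations of WTO and WTY samples from their group means correlated at 0.485, 0.260 and 0.257 across genes for numbers 3, 4 and 5. Only number 3 shares a pool. The deviations were not adjusted for pool, and WTO.3 and WTY.3 are the WBM_1 samples of their groups. HRY.4, also of WBM_1, correlated at -0.559 with WTY.4 and -0.311 with WTO.4, which lie in other pools. These correlations therefore cannot tell pairing by number from the pool. Gene positions were taken from the GENCODE vM21 annotation of GRCm38, the build also called mm10, and all 164 named genes matched it by Ensembl identifier. Further tools were DESeq2 1.42.0, Python 3.11.15, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Alternatives covered the scaling, the filter on low counts, the pool term, the samples in the fit, the sample number as a block and DESeq2. They also covered the mitochondrial limit, doublets, hashtag settings, the clustering, Ddx3y status and each sample left out. A sample counted as Ddx3y-positive when this Y-linked gene exceeded 10 CPM over all its cells. Positive were 1 of 6 HRO, 3 of 4 WTO, 3 of 3 HRY, 2 of 3 WTY and 1 of 2 chronic samples. This status therefore moved with the groups, and the tests of class shares took no account of it.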

Results

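Whole bone marrow of mice was profiled by single-cell RNA sequencing in 7 libraries of 4 pools (WBM_1 to WBM_4), in which 20 hashtag samples could be told apart. The series title concerns inflammation and the plasticity of tumour cells as myeloid cells transform. Sample names give the groups: WTY (3 samples), WTO (4), HRY (3), HRO (6), and HRO.5 and HRO.6 (2), which the series text calls TET2-mutated chronic samples and which are called chronic here. What the prefixes stand for is not stated and is not interpreted. HR.7 and HR.AE stand alone. WBM_1 held WTY.3, WTO.3, HRY.4 and both chronic samples; WBM_2 held HRO.7, HRO.8, HRO.9, WTO.4 and HR.AE; WBM_3 held WTY.4, WTY.5, HRY.5, HRY.6, HR.7 and HRO.10; WBM_4 held WTO.5, WTO.6, HRO.11 and HRO.12. Libraries held 25343305 to 95553827 UMIs, and the kept cells of a sample 2679390 (WTY.4) to 56015664 (HRO.7) UMIs in 928 (WTY.4) to 5530 (HRO.7) cells. The labels do not say that each hashtag marks a separate animal, so p-values measure the spread between hashtag samples, which may be technical.

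The makeup of the marrow was compared first. HRO samples held more monocytes (19.7% ± 7.90, SD, n = 6) than WTO samples (10.1% ± 2.59, n = 4), more T or NK cells (8.53% ± 2.56 against 3.63% ± 1.32). They also held more macrophages (1.60% ± 1.66 against 0.0323% ± 0.0474) and fewer B lineage cells (2.75% ± 2.60 against 14.1% ± 13.2). The WTO mean for B lineage cells rests on WTO.3 (33.2%), whose pool holds no HRO sample, with 5.02% to 12.6% in the other 3. Exact two-sided permutation tests over 210 splits gave p = 0.0286, 0.0190, 0.00952 and 0.0381. Each had an adjusted p of 0.124 over 13 classes, so none of these differences passed. The p for macrophages, 0.00952, is the smallest that 210 splits allow, so no class could pass alone after this adjustment. Ddx3y status, positive in 1 of 6 HRO and 3 of 4 WTO samples, did not enter these tests. The mean differences had the same sign within WBM_2 (3 HRO samples against 1), where T or NK cells were 9.53% against 3.97% and monocytes 20.7% against 13.1% (HRO.8 11.9%), and within WBM_4 (2 against 2), where they were 9.25% against 2.64% and 13.4% against 7.98%. For B lineage cells they were 4.28% against 5.62% in WBM_2, with HRO.7 at 7.09%, and 1.65% against 8.83% in WBM_4. Most of these HRO.7 cells lay in cluster 30, whose 483 cells all came from WBM_2 and to 78.5% from HRO.7. That cluster is led by Ccl22, Shisa8, Ly6k and Cd36, with 1 B lineage marker among its top 10 genes. Macrophages lay in a single cluster, number 34, whose leading genes include Saa3 and Cxcl9 beside the complement genes C1qa, C1qb and C1qc, and 65.7% of its cells came from HRO.7. Mature neutrophils made up 17.8% ± 14.4 of HRO and 31.9% ± 15.1 of WTO cells (exact permutation p = 0.171), with 1.09% in HRO.7 and 1.08% in HRO.8. Unnamed clusters held 14.4% of HRO.7 and 13.5% of HRO.8, and at most 4.29% of any other sample in the groups compared.

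Chronic samples held 17.1% ± 8.32 B lineage cells (n = 2) against 2.75% ± 2.60 in HRO (n = 6), and 2.25% ± 0.34 plasma cells against 0.642% ± 0.602. No macrophage was found among 1166 cells of HRO.5 and 3139 of HRO.6, which allows shares of up to 0.316% and 0.117% (exact Clopper-Pearson limits, counting error only). None was found in WTO.3, HRY.4 or WTY.3 of the same pool either. At resolution 2, 13% of the 453 cells named macrophages came from WBM_1, so these zeros depend on the clustering. Each of these 3 differences had p = 0.0714 by exact permutation, the smallest that 28 splits allow, so this comparison could not pass the threshold. No pool holds both groups. Within WBM_1 the chronic mean for B lineage cells, 17.1%, lay between WTY.3 (11.6%) and HRY.4 (23.3%), with WTO.3 at 33.2%, and plasma cells were 2.25% against 0.396%, 0.265% and 0.904%. In the other 8 pairs of groups no class passed either. The smallest adjusted p was 0.155 for HRO against WTY and 0.310 for HRO against HRY. In both, the 84 splits of the exact permutation test allow no p below 0.0238, so no class could pass alone after adjustment. The remaining pairs with 2 or 3 samples a side could not go below p = 0.1 in exact permutation tests, apart from HRY or WTY against WTO.

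**Figure D1:**
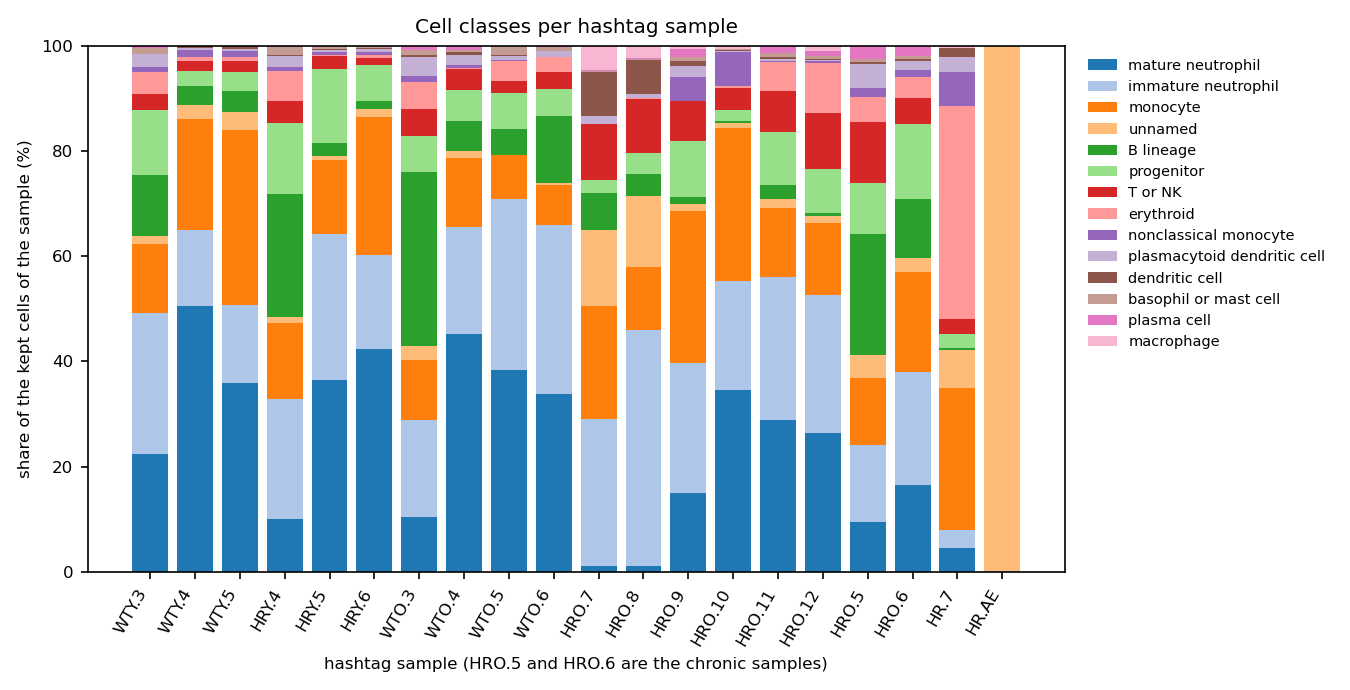
Share of the kept cells of each hashtag sample (vertical axis, percent) in each cell class, as stacked bars for the 20 samples ordered by group (horizontal axis). HRO.7 and HRO.8 hold 1.09% and 1.08% mature neutrophils, and nearly all cells of HR.AE (99.5%) lie in unnamed clusters.

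Tet2, which encodes a dioxygenase that oxidises 5-methylcytosine (ENSMUSG00000040943, GRCm38 chromosome 3, 133463679 to 133545139, minus strand, protein coding), was measured in monocytes of every group. Its level was 62.4 CPM in HRO.5 and 42.8 CPM in HRO.6, against 58.4 to 104 CPM in the other HRO samples, 44.4 to 68.7 CPM in WTO, 49.6 to 126 CPM in HRY and 43.0 to 125 CPM in WTY. The log2 fold change of chronic over HRO was 0.06 ± 0.22 in monocytes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.947). Reads of this kit come from the 3′ end of transcripts, and the mutation itself is not described, so this level says nothing about the label.

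In monocytes, the contrast the series text points to is chronic (n = 2) against the other HRO samples (n = 6). Cd38, an NAD-consuming surface enzyme of activated immune cells, was lower in the chronic samples by a log2 fold change of -5.09 ± 0.86 (SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0222). Its direction rests on HRO.10, without which the fold was 3.66 with no call. Lcn2, a secreted siderophore-binding protein of neutrophil granules, fell by 2.44 ± 0.38 (adjusted p = 0.0222 in the same test), Fcgr1, the high-affinity receptor for IgG, by 2.60 ± 0.46, and Il18rap, a subunit of the interleukin-18 receptor, by 2.21 ± 0.43. Further falls were Wfdc21 -3.50 ± 0.66, Zfp36l1 -3.45 ± 0.66, an RNA-binding protein that promotes mRNA decay, Bcl3 -2.25 ± 0.41, a partner of NF-kB p50, Chil3 -2.18 ± 0.42 and Clec4e -1.93 ± 0.37, a receptor for mycobacterial glycolipid. Zbtb20 (1.74 ± 0.33) and Zfp652 (1.41 ± 0.27), both zinc finger proteins, rose. In all, 22 of 10364 genes changed, 3 higher and 19 lower, with 1207 at an unadjusted p under 0.05.

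The chronic samples share no pool with HRO, so the fit sets their distance from WTY.3, WTO.3 and HRY.4 of WBM_1 against the distance of HRO from the same groups in other pools. Within WBM_1 the 19 lower genes had a median log2 difference of 0.10 between the chronic samples and those 3 samples. There 8 of the 19 were lower, with Bcl3 at -1.05, while Cd38 was higher in the chronic samples by 1.84 and Zfp36l1 by 0.98. Outside WBM_1, Cd38 was higher by 4.81 in HRO than in WTO, WTY and HRY. Lcn2 shows the gap between fit and level: 1169 and 1443 CPM in the chronic samples and 542 ± 192 CPM in HRO, while other WBM_1 samples had 1057 to 1584 CPM. Without the pool term 4 of the named directions turned, with Wfdc21 at 2.44, Lcn2 at 1.71, Chil3 at 0.82 and Zbtb20 at -0.021. Nearly all chronic monocytes (99.2%) lay in cluster 8, of which 93.5% came from WBM_1. HRO monocytes instead lay on average in clusters 6 (45.5%) and 10 (34.0%), the latter holding nearly all those of HRO.7 and HRO.8 (99.2% and 98.7%). The count was 0 without HRO.5, HRO.6 or HRO.10, 5 without HRO.12, 13 without HRO.8 and 73 without HRO.9, so no named gene was called in every such fit. It was 1 with hashtag counts normalised within each cell, 7 with Ddx3y status as a term and 223 without the pool term, of which 2 were among the 22.

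Of the 16 gene lists, 7 passed camera at its preset correlation in chronic against HRO monocytes, and none held with an estimated correlation. The type I interferon list (23 measured) had a median log2 fold change of -1.43, with 0 members past the threshold over all genes and 10 lower adjusted over the list alone (adjusted p = 1.85e-05, and adjusted p = 0.619 with an estimated correlation). Its strongest members were Zbp1 (-2.13 ± 0.47), a sensor of nucleic acids, Oasl2 (-2.20 ± 0.49) and Rtp4 (-2.02 ± 0.45), each short of the threshold over all genes. Antigen presentation and interferon gamma genes (22 measured) had a median of -1.39 with no member past either threshold (adjusted p = 0.00231, and adjusted p = 0.631 with an estimated correlation). Glycolysis genes had a median of -0.62, 0 over all genes and 7 lower adjusted over the list alone (adjusted p = 0.00725, and adjusted p = 0.619 with an estimated correlation), among them Tpi1 (-1.07 ± 0.22) and Ldha (-0.81 ± 0.22). NF-kB genes had a median of -0.68 and Clec4e as the 1 member lower over all genes and adjusted over the list alone (adjusted p = 0.0123, and adjusted p = 0.619 with an estimated correlation). DNA methylation enzymes had a median of 0.13, with Dnmt3a (1.78 ± 0.42) as the 1 member higher adjusted over the list alone and 0 over all genes (adjusted p = 0.0345, and adjusted p = 0.375 with an estimated correlation). Alarmins (-0.42, 0 over all genes and 2 lower adjusted over the list alone) had an adjusted p of 0.0123, and adjusted p = 0.619 with an estimated correlation. Neutrophil transcripts, a list for free RNA (-0.88, 1 lower over all genes and 4 adjusted over the list alone), had an adjusted p of 0.00231, and adjusted p = 0.375 with an estimated correlation. Beside these lists stands the level of the neutrophil alarmin S100a8 in monocytes, 24780 to 29430 CPM in the WBM_1 samples (n = 5) and 659 to 5740 CPM outside them (n = 14). Without HRO.6, 1 list passed.

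In neutrophils single genes differed between chronic and HRO samples. In immature neutrophils Ifi27l2a, an interferon-induced mitochondrial protein, was the 1 gene of 9273 that changed (log2 fold change -3.37 ± 0.45, adjusted p = 0.00454, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 against 6 samples). The call was lost without HRO.5, HRO.6 or HRO.10 (0 genes each), and 4 genes passed without HRO.9. In mature neutrophils 7 of 7018 genes changed. The ubiquitin-like interferon product Isg15 (-2.29 ± 0.45, adjusted p = 0.0382 in the same test) and Chil3 (-1.89 ± 0.36) fell, while Fgl2 (2.62 ± 0.42), Sirpb1b (2.69 ± 0.42), Ptms (2.27 ± 0.41), Steap4 (4.54 ± 0.87), a metalloreductase, and the hormone Retn rose. No gene passed without HRO.6 or HRO.10, 27 passed without HRO.9, and 2 passed without the pool term. Most WBM_1 neutrophils lay in clusters of their own: 94.9% of cluster 7 (mature), 94.8% of cluster 9 and 91.9% of cluster 20 (both immature) came from that pool. In progenitors no gene of 9923 changed by edgeR or by DESeq2, with 450 at an unadjusted p under 0.05 in edgeR, while 5 passed without HRO.9 and 1 without HRO.8.

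The type I interferon list passed camera in all 3 of these classes at the preset correlation. Its median log2 fold change in chronic against HRO was -1.81 in immature neutrophils (1 lower over all genes, 2 adjusted over the list alone, adjusted p = 7.74e-07, and adjusted p = 0.877 with an estimated correlation). In mature neutrophils it was -1.42 (1 lower over all genes, 11 adjusted over the list alone, adjusted p = 6.42e-10, and adjusted p = 0.299 with an estimated correlation). In progenitors it was -1.45 (0 over all genes, 1 adjusted over the list alone, adjusted p = 3.42e-08, and adjusted p = 0.366 with an estimated correlation). Rtp4 had log2 fold changes of -3.35 ± 1.27 in immature neutrophils and -2.86 ± 0.83 in progenitors, neither past the threshold. Antigen presentation genes had medians of -1.20, -0.81 and -0.97 in the 3 classes, with 0 members past the threshold over all genes in each and 3, 1 and 0 lower adjusted over the list alone. Their adjusted p was 0.00956, 0.000998 and 2.21e-05, and adjusted p = 0.920, 0.601 and 0.811 with an estimated correlation. Immediate early genes had medians of -0.29 in immature neutrophils and -0.40 in progenitors, with 0 members past either threshold, over all genes or adjusted over the list alone (adjusted p = 0.00431 and 0.00788, and adjusted p = 0.912 and 0.811 with an estimated correlation). Secondary granule genes in mature neutrophils had a median of -0.77, with Chil3 as the 1 member past the threshold over all genes and adjusted over the list alone (adjusted p = 0.000168, and adjusted p = 0.601 with an estimated correlation). The neutrophil transcripts had a median of -0.88 with 0 members past either (adjusted p = 0.0105, and adjusted p = 0.635 with an estimated correlation). Without HRO.6 the lists that passed numbered 1 in immature neutrophils, 2 in mature neutrophils and 5 in progenitors, and 2 passed in mature neutrophils without HRO.10.

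Monocytes of the chronic samples showed no gene past the threshold against WTO (n = 4), HRY (n = 3) or WTY (n = 3) by edgeR's quasi-likelihood test, with 466, 421 and 454 genes at an unadjusted p under 0.05. DESeq2 gave 2, 0 and 0 genes, and 1 gene passed against WTO without WTO.3. Saa3, an acute-phase apolipoprotein picked out after its values were seen, stood at 247 and 182 CPM in the chronic samples and at 2.61, 23.2 and 60.5 CPM in WTO.3, HRY.4 and WTY.3 of the same pool, with no call in any of the 3 comparisons. The interferon list was the 1 list that passed against WTO, with a median of -0.68 and 0 members past the threshold over all genes or adjusted over the list alone (adjusted p = 0.00142, and adjusted p = 0.994 with an estimated correlation). No list passed against HRY or WTY. Against WTO 0 lists passed without HRO.6 and 3 without WTO.3, against HRY 1 without HRY.4, and against WTY 1 without HRO.5.

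HRO monocytes differed from WTO monocytes (n = 6 and 4) in 946 of 10364 genes, 522 higher and 424 lower in HRO. The acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) rose from 3.19 ± 4.79 CPM (SD) in WTO to 763 ± 546 CPM in HRO (log2 fold change 7.71 ± 0.69, adjusted p = 7.61e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It stood at 197 CPM or more in each HRO sample and at most 10.1 CPM in each WTO sample. Cd38 (ENSMUSG00000029084, chromosome 5, 43868553 to 43912375) rose from 1.58 ± 1.14 to 53.9 ± 26.1 CPM (log2 5.19 ± 0.44, adjusted p = 8.42e-07 in the same test). Genes induced by interferon gamma rose too: the GTPase Iigp1 (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634) by 7.03 ± 1.82, the chemokine Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) by 6.08 ± 1.62 and the class II gene H2-Eb1 by 5.57 ± 1.62. These 3 were carried by HRO.7 and HRO.8: Cxcl9 stood at 393 and 401 CPM there and at 0.363 to 26.2 CPM in the other 4 HRO samples, and their calls were lost without both samples. Upp1 (6.06 ± 1.57), a uridine phosphorylase, Ly6a (5.69 ± 1.22), the antigen also known as Sca-1, and Emp1 (5.65 ± 1.20) completed the rises. The chemokine receptor of patrolling monocytes Cx3cr1 fell from 133 ± 51.5 to 38.7 ± 14.1 CPM (log2 -1.57 ± 0.25). Falls were also seen for the progenitor antigen Cd34 (-1.53 ± 0.32), the calcium pump Atp2b4 (-1.46 ± 0.20), the kinase Camk1 (-1.38 ± 0.24), Stxbp6 (-1.81 ± 0.32), Klrb1f (-1.57 ± 0.27), Smim5 (-1.38 ± 0.30) and Zfp467 (-1.30 ± 0.23).

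Of the 775 genes called without the WBM_4 samples, 88.0% had the same sign within WBM_4 (2 HRO samples against 2), where their median log2 difference was 0.34, against 1.05 in that fit. Cell quality moved with this contrast: the mitochondrial limit removed 16.9%, 14.9% and 10.5% of HRO.7, HRO.8 and HRO.9 against 2.39% of WTO.4 in WBM_2, and 10.5% and 6.95% of HRO against 6.49% and 5.01% of WTO in WBM_4. Kept cells, over all classes, had median mitochondrial shares of 2.40% to 3.41% against 1.23% in WBM_2 and 1.32% to 1.38% against 0.713% to 0.828% in WBM_4. The count was 63 without WTO.4, 519 without HRO.10, 544 without WTO.3 and 1672 without HRO.9. Of the 16 genes named, Saa3, Cd38, Atp2b4 and Camk1 passed in every fit with a sample left out. The count was 76 without the pool term and 450 without the WBM_1 samples. Monocytes of HRO.7 and HRO.8 lay in cluster 10 (99.2% and 98.7%), which is led by Iigp1, Cxcl9 and Saa3 themselves and came to 78.3% from HRO.7. In HRO.9 to HRO.12, 49.8% to 85.6% of monocytes lay in cluster 6 and 0% to 3.90% in cluster 10. WTO monocytes lay on average in clusters 13 (25.7%), 8 (25.7%), 16 (23.2%) and 6 (15.4%). The value for cluster 8 rests on WTO.3 (99.2%), with at most 2.21% in the other WTO samples.

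**Figure D2:**
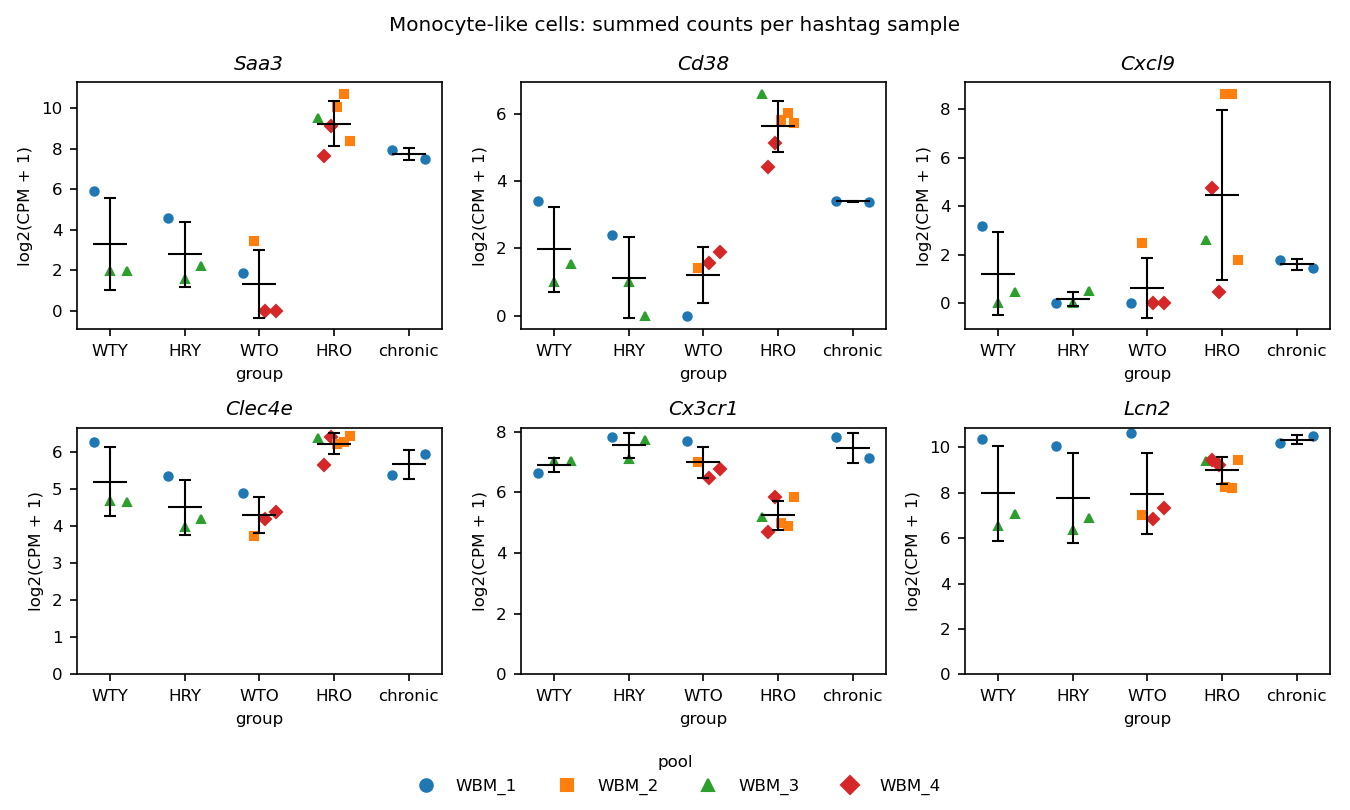
Level of 6 genes in the summed monocytes of each hashtag sample (vertical axis, log2 of CPM plus 1) by group (horizontal axis), with 1 point per sample, symbols for the pool, and bars for the mean and SD of the group. Saa3 is at 197 CPM or above in each HRO sample and at or below 10.1 CPM in each WTO sample, while Lcn2 is higher in the WBM_1 samples (1057 to 1584 CPM) than in the rest (80.0 to 702 CPM).

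Of the 16 lists, 11 passed camera at its preset correlation in HRO against WTO monocytes, and none held with an estimated correlation. Antigen presentation and interferon gamma genes (22 measured) had a median log2 fold change of 2.10, with 11 higher over all genes and 20 adjusted over the list alone, among them the class I gene H2-D1 (0.60 ± 0.16) and the proteasome subunit Psmb8 (0.92 ± 0.25) (adjusted p = 3.61e-07, and adjusted p = 0.335 with an estimated correlation). HRO.7 and HRO.8 carried this list: its mean level, in log2(CPM + 1), was 9.15 and 9.17 there, 5.19 to 6.83 in the other HRO samples and 4.76 to 5.67 in WTO, and HRO.9 (5.53) lay below WTO.4 (5.67) of its pool. NF-kB and cytokine genes (23 measured, median 1.11) had 6 higher and 1 lower over all genes and 13 higher and 1 lower adjusted over the list alone (adjusted p = 2.56e-06, and adjusted p = 0.335 with an estimated correlation). They included Clec4e (2.45 ± 0.23, adjusted p = 1.54e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Ccrl2 (2.63 ± 0.46), the neutrophil attractant Cxcl2 (2.52 ± 0.53) and Ier3 (1.98 ± 0.39). Immediate early genes (median 0.82), which also rise when tissue is dissociated, had 5 higher over all genes and 12 adjusted over the list alone, with Egr1 at 2.62 ± 0.60 and Atf3 at 1.68 ± 0.36 (adjusted p = 4.03e-06, and adjusted p = 0.335 with an estimated correlation). Their mean level was 7.78 to 7.95 in HRO against 5.71 in WTO.4 of WBM_2, but overlapped in WBM_4 (7.25 and 7.56 against 7.52 and 6.99). Glycolysis genes (median 0.64) had 10 of 15 higher over all genes and 12 higher and 1 lower adjusted over the list alone, with Ldha at 0.80 ± 0.12 and Pkm at 0.74 ± 0.11 (adjusted p = 3.61e-07, and adjusted p = 0.232 with an estimated correlation). Type I interferon genes (median 0.78) had 3 of 23 higher over all genes, Zbp1 (1.58 ± 0.28), Rtp4 (1.45 ± 0.32) and Oasl2 (1.06 ± 0.30), and 5 adjusted over the list alone (adjusted p = 0.0395, and adjusted p = 0.604 with an estimated correlation). In WBM_2 the mean level of the interferon list was 6.62 in HRO.7, 6.67 in HRO.8 and 5.33 in HRO.9, against 5.27 in WTO.4. In WBM_4 it was 3.46 and 3.68 in HRO against 3.99 and 3.53 in WTO. HRO.10 stood at 6.32, with 4.26 to 4.92 in the other samples of WBM_3, which holds no WTO sample.

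Secondary granule genes (median 0.48) had 4 higher and 1 lower over all genes and 5 higher and 1 lower adjusted over the list alone, with Lcn2 at 2.12 ± 0.24 and Chil3 at 1.40 ± 0.26 (adjusted p = 0.00994, and adjusted p = 0.283 with an estimated correlation). Alarmins (median 0.30) had 2 higher over all genes, S100a8 (1.82 ± 0.25) and S100a9 (1.41 ± 0.28), and 4 adjusted over the list alone (adjusted p = 0.0022, and adjusted p = 0.335 with an estimated correlation). The neutrophil transcripts that mark free RNA (median 0.79) had 4 of 7 higher over all genes and 5 adjusted over the list alone (adjusted p = 5e-05, and adjusted p = 0.232 with an estimated correlation). Without the pool term S100a8 was -1.23 and Lcn2 -0.15 on the log2 scale, since WBM_1, which holds WTO.3, had S100a8 at 24780 CPM or more in monocytes of each sample (n = 5) and the other pools at most 5740 CPM (n = 14). Cell cycle genes (median -0.28) had 2 lower over all genes, Cenpf (-0.60 ± 0.14) and Ube2c (-0.53 ± 0.15), and 9 adjusted over the list alone (adjusted p = 0.00202, and adjusted p = 0.349 with an estimated correlation). The stem and leukaemia list (median -0.33) had 3 lower, namely Bcl2 (-1.06 ± 0.21), Cd34 and Myb (-0.80 ± 0.23), and 1 higher over all genes, and 4 lower and 2 higher adjusted over the list alone (adjusted p = 0.0496, and adjusted p = 0.335 with an estimated correlation). The mean level of this list was 2.58 to 3.15 in HRO against 3.58 in WTO.4 of WBM_2, and not lower in WBM_4 (3.97 and 3.68 against 3.74 and 3.64). Among DNA methylation enzymes (median -0.30) the methyltransferase Dnmt3a fell (-1.07 ± 0.16), the 1 member past the threshold over all genes. In this list 3 were lower and 1 higher adjusted over the list alone (adjusted p = 0.0334, and adjusted p = 0.232 with an estimated correlation). Tet2 was at 0.29 ± 0.12 (adjusted p = 0.12 by edgeR's test). Lists that did not pass were primary granule genes (adjusted p = 0.676), monocyte identity (0.699), macrophage identity (0.200), suppressive myeloid genes (0.0547) and haemoglobins, the list for free red cell RNA (0.907). Without WTO.4, 4 lists passed.

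**Figure D3:**
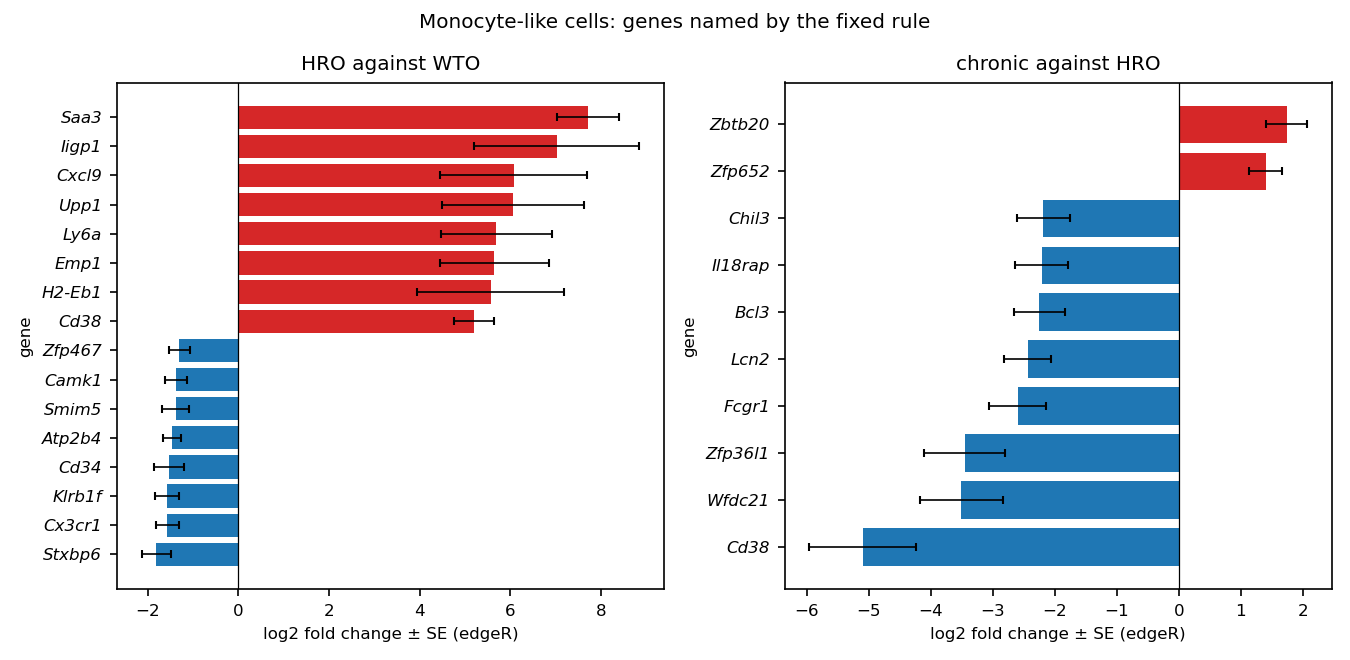
Log2 fold changes (horizontal axis) from edgeR, with SE bars derived from the F values of its test, for the genes that the fixed rule names in monocytes. HRO against WTO is at left and chronic against HRO at right. Saa3 has the highest value at left (7.71 ± 0.69) and Cd38 the lowest at right (-5.09 ± 0.86).

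In immature neutrophils 247 of 9273 genes differed between HRO and WTO (6 against 4 samples), 184 higher and 63 lower. Among the largest rises were the GTPase Gbp2 (5.0 ± 1.13, adjusted p = 0.0149, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Oasl2 (3.69 ± 0.84), Rtp4 (3.30 ± 0.56), Zbp1 (3.07 ± 0.69), Xaf1 (2.78 ± 0.63) and Ifi27l2a (1.74 ± 0.29), together with BC100530 (3.28 ± 0.70). The class I genes H2-Q6 (4.54 ± 0.78) and H2-Q7 (4.33 ± 0.70) also rose, but are near-identical copies whose reads may be shared. Immediate early genes rose, with Klf2 at 1.47 ± 0.14, Dusp1 at 2.27 ± 0.29 and Egr1 at 2.39 ± 0.35, and so did the chemokines Ccl3 (2.13 ± 0.26) and Cxcl2 (2.41 ± 0.33). The largest fall was in the matrix protein Thbs1 (-1.77 ± 0.42), followed by Rap2a (-0.78 ± 0.14), Cfdp1 (-0.59 ± 0.12) and Igf2r (-0.58 ± 0.11). The count was 17 without WTO.4, 153 without HRO.11, 156 without WTO.5 and 551 without HRO.9, and 0 genes passed without the pool term. Of the 16 genes named by size 0 passed in every fit with a sample left out, and 12 passed without both HRO.7 and HRO.8. Loss of cells to the mitochondrial limit, which moved with the groups in both pools (over all classes, 2.39% of WTO.4 against 10.5% to 16.9% of HRO in WBM_2), stands beside the rise of immediate early genes. HRO.7 gave 53.7% of cluster 5 and 57.0% of cluster 23, both immature neutrophils.

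Of the lists, 7 passed camera in immature neutrophils of HRO against WTO. Immediate early genes (median 1.21) had 11 of 16 higher over all genes and 13 adjusted over the list alone, and this list alone passed with an estimated correlation too (adjusted p = 1.71e-18, and adjusted p = 0.0491 with an estimated correlation). Type I interferon genes (median 1.91) had 10 of 20 higher over all genes and 19 adjusted over the list alone (adjusted p = 4.17e-14, and adjusted p = 0.0845 with an estimated correlation). Antigen presentation genes (median 1.20) had 7 and 15 higher adjusted over the list alone (adjusted p = 1.24e-10, and adjusted p = 0.224 with an estimated correlation), with H2-K1 at 1.94 ± 0.38 and the peptide transporter Tap1 at 1.87 ± 0.38. NF-kB genes (median 0.67) had 7 higher over all genes and 13 higher and 1 lower adjusted over the list alone (adjusted p = 1.67e-08, and adjusted p = 0.0845 with an estimated correlation). Primary granule genes (median 0.39) had 2 higher over all genes and 2 adjusted over the list alone, 1 of them the proteoglycan Srgn (1.02 ± 0.13) (adjusted p = 9.29e-05, and adjusted p = 0.0845 with an estimated correlation). Monocyte identity genes (median 0.30, 0 past the threshold over all genes or adjusted over the list alone) had an adjusted p of 0.0455, and adjusted p = 0.224 with an estimated correlation. Haemoglobins, the list for free red cell RNA (median 0.34), had Hba-a2 (0.76 ± 0.19) higher over all genes and adjusted over the list alone (adjusted p = 0.0234, and adjusted p = 0.224 with an estimated correlation). Without the pool term Hba-a2 was at -1.57.

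In mature neutrophils 102 of 7018 genes differed, 79 higher and 23 lower in HRO (6 against 4 samples). The rises included Ccrl2 (2.93 ± 0.41, adjusted p = 0.000264, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a receptor for chemerin, Cd14 (2.63 ± 0.52), a co-receptor for bacterial lipopolysaccharide, the protease inhibitor Stfa2 (3.01 ± 0.40), Gbp2b (2.59 ± 0.61), Isg15 (1.28 ± 0.24) and Rtp4 (1.11 ± 0.19). Higher too were the class I genes H2-Q6 (4.20 ± 0.69), H2-Q7 (3.57 ± 0.59) and H2-Q4 (2.82 ± 0.50), whose reads may be shared among copies. Smooth muscle actin Acta2 (-1.55 ± 0.25), Thbs1 (-1.55 ± 0.36), the complement receptor C5ar2 (-1.15 ± 0.28) and Creg1 (-0.73 ± 0.14) fell. The count was 44 without WTO.4, 54 without HRO.11, and 60 without WTO.5 or without WTO.6, and 1 gene passed without the pool term. The mature neutrophils lay in several clusters: WTO.4 gave 22.7% of cluster 1 and 42.8% of cluster 2, and HRO.9 gave 23.3% of cluster 4. Of the lists, 4 passed camera, and none held with an estimated correlation. Type I interferon genes had a median of 0.89 (7 of 21 higher over all genes, 15 adjusted over the list alone, adjusted p = 1.27e-17, and adjusted p = 0.0590 with an estimated correlation). Antigen presentation genes had a median of 0.75 (6 higher over all genes, 11 adjusted over the list alone, adjusted p = 6.87e-14, and adjusted p = 0.0708 with an estimated correlation). Immediate early genes had a median of 0.78 (6 higher, 11 adjusted over the list alone, adjusted p = 5.59e-11, and adjusted p = 0.0940 with an estimated correlation). Beside it stands the mitochondrial loss in WBM_2, 10.5% to 16.9% of HRO cells against 2.39% of WTO.4 cells, over all classes. NF-kB genes had a median of 0.39 (5 higher and 1 lower, the same numbers adjusted over the list alone, adjusted p = 0.0413, and adjusted p = 0.586 with an estimated correlation). Without HRO.11, 7 lists passed.

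In progenitors 26 of 9923 genes differed, 22 higher and 4 lower in HRO (6 against 4 samples). Iigp1 rose by 4.46 ± 0.83 (adjusted p = 0.0155, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 1.45 ± 1.62 CPM in WTO to 54.7 ± 40.8 CPM in HRO. Klf2, a transcription factor of quiescence, rose by 2.38 ± 0.30 (adjusted p = 0.0013 in the same test). Irf7 (2.56 ± 0.44), the master regulator of interferon genes, Ifitm3 (1.48 ± 0.29), a restriction factor for viruses, Serpina3g (2.34 ± 0.39), Jund (1.47 ± 0.24) and the class I genes H2-Q7 (2.59 ± 0.40), H2-Q6 (2.49 ± 0.39) and H2-Q4 (1.78 ± 0.34) rose as well. The lectin Mgl2 (-0.88 ± 0.15) and Tmcc1 (-0.77 ± 0.12) fell. The count was 3 without WTO.4, 13 without WTO.5, 16 without WTO.6, 48 without HRO.11 and 180 without HRO.9, and among the 10 genes named by size only Klf2 passed in every such fit. It was 1 when only the 2 groups were fitted, 101 without both HRO.7 and HRO.8 and 6 at a mitochondrial limit of 5%, and the mitochondrial shares of these samples moved with the groups as given for monocytes. Of the lists, 5 passed camera. Antigen presentation genes had a median of 1.13 (3 of 21 higher over all genes, 16 adjusted over the list alone, adjusted p = 4.2e-21), immediate early genes 1.04 (3 and 12, adjusted p = 8.8e-14), type I interferon genes 1.33 (2 and 10, adjusted p = 3.77e-12) and NF-kB genes 0.69 (0 and 9, adjusted p = 2.74e-08), each with adjusted p = 0.0583 with an estimated correlation. Cell cycle genes had a median of -0.20, with 0 members past the threshold over all genes and 0 lower adjusted over the list alone (adjusted p = 0.000801, and adjusted p = 0.373 with an estimated correlation).

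The remaining pairs of groups were compared in monocytes. Against HRY (n = 3), HRO monocytes differed in 480 genes, 303 higher and 177 lower, and again showed higher Saa3 (7.78 ± 0.85, adjusted p = 7.51e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Cd38 (6.96 ± 0.59). Without HRO.10 the fold of Cd38 turned to -2.19. Socs3, a feedback inhibitor of cytokine signalling, rose by 5.24 ± 0.68, Lrg1 by 5.56 ± 1.35, Ifitm1 by 4.13 ± 0.42 and Zfp36l1 by 4.28 ± 0.47. The arginine deiminase Padi2 (-3.20 ± 0.37), the neonatal Fc receptor Fcgrt (-2.34 ± 0.36), Ldhb (-2.20 ± 0.29) and Cx3cr1 (-1.98 ± 0.39) fell. Of the lists, 9 passed camera and none held with an estimated correlation. Type I interferon genes had a median of 1.77, with 12 of 23 higher over all genes and 16 adjusted over the list alone (adjusted p = 1.02e-09, and adjusted p = 0.256 with an estimated correlation). Glycolysis genes had a median of 0.71, with 7 higher over all genes and 11 higher and 1 lower adjusted over the list alone (adjusted p = 3.52e-05, and adjusted p = 0.263 with an estimated correlation). Antigen presentation genes had a median of 1.33 (1 higher over all genes, 5 adjusted over the list alone, adjusted p = 9.56e-05, and adjusted p = 0.497 with an estimated correlation). NF-kB genes, immediate early genes, granule genes, alarmins, DNA methylation enzymes and neutrophil transcripts made up the other 6 lists, with adjusted p = 0.137 to 0.530 with an estimated correlation. HRO and HRY share a pool only through HRO.10: the count was 2 without it, 842 without HRO.9, and 259, 249 and 267 without HRY.4, HRY.5 and HRY.6. It was 225 without the pool term, 138 with only the 2 groups in the fit, and 254 without the WBM_1 samples.

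Against WTY (n = 3), HRO monocytes differed in 364 genes, 243 higher and 121 lower. Saa3 (6.87 ± 0.83, adjusted p = 0.000272, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Cd38 (5.44 ± 0.51), Ifitm1 (4.31 ± 0.43), Socs3 (4.22 ± 0.60) and the interferon-induced Ifi44 (6.60 ± 1.34) rose. Without HRO.10 Cd38 was at -3.71. Padi2 (-3.21 ± 0.37), Fcgrt (-2.47 ± 0.35) and Zbtb20 (-2.05 ± 0.23) fell. Of the 8 lists that passed camera, type I interferon genes had a median of 1.69, with 8 of 23 higher over all genes and 17 adjusted over the list alone (adjusted p = 5.93e-09, and adjusted p = 0.296 with an estimated correlation). Glycolysis genes had a median of 0.88, with 9 and 11 (adjusted p = 6.2e-06, and adjusted p = 0.296 with an estimated correlation). The other 6 had adjusted p = 0.243 to 0.656 with an estimated correlation. HRO and WTY share a pool only through HRO.10. The count was 1 without it, 733 without HRO.9, 90 without WTY.4 and 96 without WTY.5, and 570 with DESeq2; 5 lists passed without HRO.10.

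WTO and WTY monocytes (n = 4 and 3) differed in 2 genes: the cell adhesion protein Nectin1 (-2.79 ± 0.39, adjusted p = 0.0172, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Gm35082 (-7.14 ± 0.99) were lower in WTO. With the sample number as a block 2 genes passed and 0 of them were the same, and 0 passed without WTO.4, WTO.6 or WTY.5 and 1 without WTY.3. The type I interferon list passed camera with a median of 0.74 (0 members over all genes, 3 higher adjusted over the list alone, adjusted p = 3.89e-07, and adjusted p = 0.938 with an estimated correlation), and 5 lists passed without WTO.3. No gene passed between HRY and WTY (n = 3 each) or between HRY and WTO by edgeR, with 684 and 645 genes at an unadjusted p under 0.05. DESeq2 gave 7 and 1, and 1 gene passed in edgeR without WTY.4 and without WTO.4. Between HRY and WTO the type I interferon list passed, with a median of -0.91 and Ifi27l2a at -2.01 ± 0.46 (0 members over all genes, 4 lower adjusted over the list alone, adjusted p = 3.63e-08, and adjusted p = 1.0 with an estimated correlation). No list passed between HRY and WTY, where 2 passed without HRY.4 and 3 without WTY.3, and between HRY and WTO 3 passed without HRY.4 and 4 without WTO.3.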

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

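Chosen only after the results were seen were the counts of other splits, the tests of HRO.7 and HRO.8 alone and of the hashtag normalisation, whereas the other tests below were written down ahead of their result.

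The change from WTO to HRO differed from the change from WTY to HRY in 173 monocyte genes, 103 higher and 70 lower (interaction in the edgeR fit), and in 7 genes of immature neutrophils, 5 of mature neutrophils and 1 of progenitors. In monocytes the difference was 8.62 ± 1.13 on the log2 scale for Saa3, 6.71 ± 0.98 for Cd38, 3.15 ± 0.35 for Clec4e, 2.32 ± 0.36 for Lcn2, -2.25 ± 0.40 for Cx3cr1 and -1.41 for Dnmt3a, all past the threshold. Iigp1 (5.91 ± 4.67), Cxcl9 (8.93 ± 4.58) and H2-Eb1 (5.54 ± 2.32) did not pass. Of 100 splits of the samples, drawn from 4200 possible, 1, the real one, gave as many monocyte genes. The highest other gave 7, so no other split drawn came near the real count. The splits exchange samples across pools, so they do not exclude chance. The interaction was not refitted with a sample left out or without the pool term, on which the count for HRO against WTO depended.

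For the 946 monocyte genes between HRO and WTO, free RNA of neutrophils was excluded as the cause of the whole, since 22.4% of the 522 risen genes were higher in neutrophils than in monocytes (95% interval 18.9% to 26.2%), close to the 20.6% of all genes tested, but it stays open for the neutrophil transcripts, which rose (median 0.79, 4 of 7 higher over all genes). Against a difference of the WBM_2 samples alone, 88.0% of the 775 genes called without WBM_4 had the same sign within WBM_4 (85.5% to 90.2%). Their median difference there was 0.34 against 1.05 in the fit. The interval treats genes as independent, while the test rests on HRO.11 and HRO.12 against WTO.5 and WTO.6, which also differ in Ddx3y status. The shared sign argues against WBM_2 alone for the direction of these genes, without excluding it for their size. HRO.7 and HRO.8 alone were excluded as the cause of the whole, since 613 of the 946 genes were called without them. So was the mix of Ddx3y-positive samples, 1 of 6 in HRO and 3 of 4 in WTO, since 699 were called with that term. This mix stays open for the genes not called with the term. Of 99 splits 3, the real one included, gave as many genes, and the highest other gave 1051. These splits exchange samples across pools, so they do not exclude chance. The deviations of HRO.7 and HRO.8 from the HRO mean correlated at 0.807 across genes. Both values point to a structure of the samples beside the groups. A mitochondrial limit of 5% left 952 genes, while cell quality in other respects, which moved with the groups, and a biological difference stay open, and the count was 63 without WTO.4 and 76 without the pool term.

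For the 22 monocyte genes between chronic and HRO samples, 3 explanations stay open. A difference of the HRO samples from all others, rather than of the chronic samples, would leave the 19 lower genes with little difference within WBM_1. Their median there was 0.10 (SE 0.13 by bootstrap over these genes), beside 1.70 for HRO over WTO, WTY and HRY outside it. The SE does not measure the spread between samples, since the difference rests on 2 chronic against 3 other samples. The genes were also picked from the same data. The mix of Ddx3y-positive samples may contribute, since 7 of the 22 genes were called with that term, and 1 of 2 chronic and 1 of 6 HRO samples are positive. Cells of other samples given to HRO.5 are a further candidate, since 1 gene was called with the other hashtag normalisation. TET2 mutation, the difference the series text names, remains untested apart from these.

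Of the HR.AE cells 99.5% lay in a single unnamed cluster, against at most 3.41% of unnamed cells in any WTY or WTO sample. The mitochondrial limit removed 6273 HR.AE singlets (66.8%), and of the 578 with 10% to 20% mitochondrial counts 99.7% fell in the same cluster. This met the bound set ahead. However, removed cells were not clustered themselves but given the majority cluster of their nearest kept cells. They could thus fall only in clusters that kept cells had formed. Cells above 20% were left out of this count and the 578 are a small part of those removed, so the limit stays open. No test was made of cells of another sample given the HR.AE hashtag. Of the cells in this cluster 94.5% carried that hashtag. Xist stood at 2.06 CPM and Ddx3y at 89.0 CPM in HR.AE, against 738 to 830 CPM and 1.11 to 1.64 CPM in HRO.7, HRO.8 and WTO.4 of its pool. These values argue against those samples as the source of the HR.AE cells as a whole. They do not set HRO.9 (5.32 and 51.5 CPM) apart, so for HRO.9 this stays open. The design gives HR.AE no replicate and no stated condition, so no biological explanation was tested.

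Immature neutrophils made up 44.9% of HRO.8, with 20.8% to 28.0% in the other 5 HRO samples, and Cxcl9 in WTO.4 monocytes was at 2.48 on the log2(CPM + 1) scale with 0 in the other WTO samples. These were the 2 found in 58 checks for a sample far from its group, and chance gives about 1 in 20. HR.7 held 40.4% erythroid cells (highest WTY or WTO sample 5.15%), 6.42% nonclassical monocytes (1.40%), 1.71% dendritic cells (0.551%), 0.464% macrophages (0.10%) and 7.10% unnamed cells (3.41%). WBM_3a and WBM_3b shared 2078 barcodes, against 51 in the next pair of libraries, with a median UMI ratio of 31.8 where WBM_3a held more and 12.7 where WBM_3b did.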

How the results depend on the processing

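Settings chosen only after the data were seen were Ddx3y status as a term, leaving out HRO.7 with HRO.8 or the WBM_1 samples, the top 5 percent of Scrublet scores, hashtag counts normalised within each cell, the lower-UMI barcode copies kept and, for gene tests, the stricter hashtag quantile and resolution 2; the others were planned. Of planned counts of changed genes 155 stayed within 1.5 times, 56 moved further, 19 rose from 0 and 13 fell to 0, and of added ones 95, 16, 3 and 1. Where no cause is given below, the cause was not tested. In simulated data 44% of 2-fold changes were recovered for chronic against HRO monocytes and 95% for HRO against WTO. What part of this is due to depth or to the number of samples was not tested. Whether these shares hold in the real data was not tested either.

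Chronic against HRO in monocytes gave 22 genes, and 41 with no filter on low counts (21 of them among the 22), 223 without the pool term (2), and 1300 with only the 2 groups and no pool term (6). The count was 7 with Ddx3y status (7), 72 without HRO.7 and HRO.8 (22), 65 with DESeq2 (10), 11 without Scrublet doublets (10). It was 10 without the top 5 percent of Scrublet scores (8), 1 with hashtag counts normalised within each cell (1), and 0 to 73 with each sample left out. Without the pool term the difference between pools enters the contrast by construction. In immature neutrophils 1 gene became 662 with only the 2 groups (0 shared), 3 without HRO.7 and HRO.8, and 0 to 4 with samples left out. In mature neutrophils 7 became 74 with no filter, 2 without the pool term, 231 with only the 2 groups, 4 with Ddx3y status, 12 with DESeq2, 3 at resolution 2, and 0 to 27. In progenitors 0 became 10 with no filter, 265 without the pool term, 1441 with only the 2 groups, 4 without HRO.7 and HRO.8, 1 at resolution 2, and 0 to 5.

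Chronic against WTO in monocytes gave 0 genes, and 1 with no filter, 6 with only the 2 groups, 2 with DESeq2 and 0 to 1 with samples left out. Against HRY and WTY, also at 0, these were 7 and 6 with only the 2 groups, and 0 to 0 with samples left out. HRO against WTO gave 946, and 76 without the pool term (all 76 among the 946), 159 with only the 2 groups, 450 without the WBM_1 samples, and 63 to 1672. HRO against HRY gave 480, and 225 without the pool term (106 shared), 138 with only the 2 groups, 819 without HRO.7 and HRO.8, 254 without the WBM_1 samples, and 2 to 842. HRO against WTY gave 364, and 775 without HRO.7 and HRO.8, 570 with DESeq2, and 1 to 733. WTO against WTY gave 2, and 0 without the pool term or at resolution 2, and 0 to 3. HRY against WTY gave 0, and 20 with only the 2 groups, 7 with DESeq2 and 0 to 1. HRY against WTO gave 0, and 1 with Ddx3y status, 3 with only the 2 groups, 1 with DESeq2 and 0 to 1. HRO against WTO gave 247 in immature neutrophils, and 0 without the pool term, 99 with only the 2 groups, 162 at resolution 2, and 17 to 551. In mature neutrophils 102 became 218 with no filter, 1 without the pool term, 54 with only the 2 groups, and 44 to 110. In progenitors 26 became 196 with no filter, 5 without the pool term, 1 with only the 2 groups, 55 with Ddx3y status, and 101 without HRO.7 and HRO.8. They became 3 without the WBM_1 samples, 54 with DESeq2, 6 at a mitochondrial limit of 5%, 139 at resolution 2, and 3 to 180. Other planned and added settings kept each of these counts within 1.5 times. A group left with 1 sample was assumed to vary like the others.

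With the sample number as a replicate block, and no pool term, chronic against WTO gave 2642 genes and against HRY 2955, fits in which the difference between pools enters the contrast. The pairs behind them correlated at -0.044 to 0.069, which gave no sign of pairing by number. WTO against WTY gave 2, none shared with the reported 2, and HRY against WTY (pairs at -0.559 and 0.532) and HRY against WTO (-0.311, 0.301 and 0.25) gave 0 each. The block changed no other call. No paired analysis was possible because the groups share fewer than 2 numbers for chronic against HRO, chronic against WTY, and HRO against WTO, HRY or WTY, and because at most 3 pairs of samples are too few for a paired exact test of class shares.

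Counts of lists that passed were, at the preset correlation, with an estimated correlation and with fry, 7, 0 and 2 for chronic against HRO in monocytes (1 to 8 with samples left out). They were 3, 0 and 0 in immature neutrophils (1 to 4), 4, 0 and 0 in mature neutrophils (2 to 5) and 3, 0 and 0 in progenitors (3 to 5). They were 1, 0 and 0 for chronic against WTO (0 to 3), 0 throughout for chronic against HRY (0 to 1) and WTY (0 to 1) and HRY against WTY (0 to 3). They were 11, 0 and 8 for HRO against WTO (4 to 12), 9, 0 and 5 for HRO against HRY (7 to 10), 8, 0 and 3 for HRO against WTY (5 to 8), and 1, 0 and 0 for WTO against WTY (1 to 5) and HRY against WTO (1 to 4). For HRO against WTO they were 7, 1 and 4 in immature neutrophils (5 to 9), 4, 0 and 0 in mature neutrophils (3 to 7) and 5, 0 and 4 in progenitors (5 to 7). The shares of cell classes passed in 0 classes for all 10 pairs in all 114 planned and 30 added values (0 to 0). Outside HRO against WTO, HRY or WTY the smallest p the splits allow was 0.0571 to 0.2, so these zeros were largely fixed by the design.

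Of named genes under planned settings, 4745 values kept direction and call, 717 lost the call, 156 gained it and 33 reversed, and of added ones 2457, 186, 59 and 0. In chronic against HRO monocytes the log2 fold change reversed without the pool term for Zbtb20 (-0.021), Wfdc21 (2.44), Lcn2 (1.71) and Chil3 (0.82). With only the 2 groups it reversed for Zbtb20 (-0.023), Wfdc21 (2.45), Lcn2 (1.72), Chil3 (0.83), S100a8 (3.12), S100a9 (3.17), S100a6 (1.62) and Ngp (3.73). Over samples left out Cd38 ranged from -5.17 without HRO.6 to 3.66 without HRO.10. In mature neutrophils with only the 2 groups Chil3 was at 0.0028. Under the block Trim30a (1.41), Rsad2 (1.92) and Oasl2 (2.09) reversed in chronic against WTO and Tet2 (-0.56) in chronic against HRY. Without the pool term Lcn2 (-0.15), Ngp (-2.10), S100a8 (-1.23) and S100a9 (-1.44) reversed in HRO against WTO. In HRO against HRY it was Wfdc21 (-0.36), Chil3 (-0.057), Ngp (-1.85), S100a8 (-1.49) and S100a9 (-1.55), in HRO against WTY S100a8 (-1.72), S100a9 (-1.78) and Lcn2 (-0.27), and Hba-a2 (-1.57) in immature neutrophils of HRO against WTO. Over samples left out Cd38 in monocytes ranged from -2.19 to 8.13 in HRO against HRY and from -3.71 to 5.93 in HRO against WTY, lowest without HRO.10 in both.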

Other observations

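All tests of other splits below were chosen after the results were seen, and the other pairs in neutrophils and progenitors were not recomputed under the alternatives or with DESeq2. HRO shares a pool with HRY and WTY through HRO.10 alone.

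HR.7, alone in its group, had a marrow rich in red cell precursors: 40.4% of its 2803 cells were erythroid (95% interval 38.6% to 42.2%), 27.0% monocytes (25.4% to 28.7%) and 4.50% mature neutrophils. Most of its erythroid cells lay in cluster 17, led by the carbonic anhydrase Car2, Tspo2 and the Rhesus glycoprotein Rhag, and 97.6% of that cluster was HR.7. Its monocytes held Lyz2 at 9115 CPM (9036 to 9195), Ly6c2 at 2839 CPM, Fn1 at 2555 CPM, the chemokine receptor Ccr2 at 1765 CPM and the proliferation marker Mki67 at 769 CPM (746 to 792). Intervals cover counting error only.

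The 1401 kept cells of HR.AE, of 9388 singlets, lay almost wholly in cluster 11 (median 16265 UMIs), which resolution 2 parts into clusters 8 and 53 and which is led by the mast cell proteases Cpa3 and Cma1 with Ctla2a, Ccl2, Scin and Cd34. The receptor Kit stood at 481 CPM (472 to 490), Cd34 at 600 CPM, the transcription factors Runx1 at 503 CPM and Gata2 at 163 CPM, Ccr2 at 556 CPM, Lgals3 at 2245 CPM and S100a6 at 3684 CPM. In contrast the primary granule gene Mpo stood at 14.0 CPM and Cx3cr1 at 0.463 CPM. Its markers tied between mast cell or basophil and progenitor, so it was left unnamed. No test was made with 1 sample.

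Mature neutrophils of HRO differed from HRY in 323 genes (171 higher, 152 lower; 6 against 3 samples) and from WTY in 229 (98 higher, 131 lower), by edgeR's quasi-likelihood test. The type I interferon list had a median of 2.12 against HRY (16 of 21 higher over all genes, 20 adjusted over the list alone, adjusted p = 1.32e-20, and adjusted p = 0.0354 with an estimated correlation). It had a median of 1.65 against WTY (14 higher, 19 adjusted over the list alone, adjusted p = 6.95e-19, and adjusted p = 0.0473 with an estimated correlation). Secondary granule genes had a median of 1.16 against HRY (7 higher over all genes, 9 adjusted over the list alone, adjusted p = 1.63e-10, and adjusted p = 0.135 with an estimated correlation). Genes named here were chosen after their values were seen: Ifit1 was at 3.56 and Lipg at 5.88 on the log2 scale in HRO against HRY. The prostaglandin synthase Ptgs2 was at -5.27 there and at -3.78 against WTY. HRY mature neutrophils differed from WTO in 98 genes, with Ptgs2 at 4.94 and Ifit1 at -2.67, and from WTY in 1 gene, Egr1 (2.21 ± 0.28). WTO differed from WTY in 63 genes, among them Ptgs2 (-3.45) and Ccrl2 (-6.88). Chronic samples differed from WTO in 4 genes, Igfbp6 (7.86 ± 1.28), Steap4 (5.41 ± 0.94), the cytokine Il1b (2.96 ± 0.54) and Fgl2 (2.36 ± 0.44).

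In immature neutrophils 11 genes were higher in HRO than in HRY, among them Ifi27l2a (4.22 ± 0.37), Oas2 (2.80 ± 0.40) and Irf9 (2.09 ± 0.32). HRO was above WTY in Ifi27l2a (3.55 ± 0.37) and Ifi27 (1.23 ± 0.20), and HRY below WTO in Ifi27l2a (-2.48 ± 0.39) and Trim30b (-2.31 ± 0.36). In progenitors Lgals3bp (2.08 ± 0.26), Ly6a (3.18 ± 0.42), Ifi44 (3.74 ± 0.58) and Ifitm3 (2.38 ± 0.39) were higher in HRO than in HRY. The first 3 were also higher than in WTY, at 1.77 ± 0.27, 2.79 ± 0.43 and 3.95 ± 0.67. These counts of 2, 2, 4 and 3 genes were again picked out after their values were seen.

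Other splits of the same samples were counted, the real one included, for each comparison of groups with 3 or more samples. In monocytes the share of splits with as many genes was under 0.05 for HRO against HRY (2 of 84, real 480 genes, highest other 1048). It was also under 0.05 for HRO against WTY (4 of 84, real 364, highest other 1037). The highest other splits, both with HRO.7, HRO.8 and HRO.10 apart from the rest, call over 2 times the real count, a structure of the samples. All splits counted here exchange samples across pools, and the shares were not adjusted over comparisons. A share under 0.05 therefore does not exclude chance. These pairs of groups are linked through HRO.10 alone (2 and 1 genes without it), so their shares do not tell a group difference from this structure either. The share was above 0.05 in monocytes for WTO against WTY (4 of 35, real 2, highest other 4) and HRY against WTO (35 of 35, real 0, highest other 10). In mature neutrophils the share was under 0.05 for HRO against WTO (1 of 99, real 102, highest other 59) and HRO against HRY (2 of 84, real 323, highest other 330). So it was for HRO against WTY (2 of 84, real 229, highest other 292). The share was above 0.05 there for WTO against WTY (2 of 35, real 63, highest other 216) and HRY against WTO (2 of 35, real 98, highest other 343). In immature neutrophils the share was above 0.05 for HRO against WTO (5 of 99, real 247, highest other 485) and HRO against HRY (22 of 84, real 11, highest other 369). It was above 0.05 too for HRO against WTY (24 of 84, real 2, highest other 309). So it was for HRY against WTO (3 of 35, real 2, highest other 8) and WTO against WTY (35 of 35, real 0, highest other 5). The same held in progenitors for HRO against WTO (14 of 99; 26, highest other 1071), HRO against HRY (23 of 84; 4, highest other 898), HRO against WTY (23 of 84; 3, highest other 985), WTO against WTY (35 of 35; 0, highest other 2) and HRY against WTO (35 of 35; 0, highest other 1). Splits that call several times the real count point to a structure of the samples that the groups do not follow. HRY against WTY allows 10 splits, too few for a share under 0.05. The real and the highest other counts were 0 and 0 in monocytes, immature neutrophils and progenitors (10 of 10 each) and 1 and 1 in mature neutrophils (3 of 10).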
